A study of Sus scrofa domesticus with 4 samples.

How the data were processed

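Gene expression was measured in explants of pig myometrium (Sus scrofa) with 4 Agilent dual-colour arrays, each hybridised with RNA of OXA-treated tissue in 1 dye and RNA of non-treated tissue in the other. The sample labels place OXA in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4, and these labels set the direction of every log ratio here. The labelling protocol's wording instead has non-treated RNA in Cy3 and OXA-treated RNA in Cy5 throughout, so that reading was run as an alternative. The labels speak of 4 individuals and of 4 separate culture experiments, and the 4 arrays were treated as 4 replicates. They do not say outright that both channels of an array came from the same animal. All 4 arrays share 1 slide and 1 scan per the file headers, so no slide or scan batch could be fitted.

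The deposited scanner files hold spot and background intensity as medians on a linear scale, with flags, written by Agilent Feature Extraction 10.7.3.1 per the file headers. They also hold the scanner's processed signal intensity and its LogRatio, a log10 ratio of Cy5 over Cy3 per the file headers. The deposited value table holds log2 ratios. Its direction and scale are not described in the labels and were found by setting each column against the scanner values of its array. The slope was 1 on arrays 1 and 3 and -1 on arrays 2 and 4, so the table runs as OXA over non-treated. At least 99.9% of tested probes lay within 0.001 of the scanner's log2 ratio. The column medians were 0.10, 0.10, -0.19 and 0.07 on arrays 1 to 4, and no further centring was found.

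Analysis started from the median signals, used here in place of the mean signals that had been planned. Background was corrected with normexp (offset 50) and ratios were normalized by loess within each array, with weight 0 for the 1417 control spots and for spots with an outlier flag, using limma 3.58.1 in R 4.3.3. Spots of a probe were averaged (50 probes had 5 spots each), which gave 43603 probes. Outlier spots numbered 107, 132, 280 and 74 on arrays 1 to 4, and no spot was saturated. A probe was tested if it was well above background on at least 3 of 4 arrays in the OXA or the non-treated channel, which held for 19505 probes (44.7%). Precision is limited by the number of arrays.

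RefSeq transcript accessions of the array design were matched, without versions, to a RefSeq gene table of assembly Sscrofa11.1, used for names alone. This named 6700 probes of 3029 genes, and 36903 probes stayed unnamed here. Of the tested probes, 4488 were named, from 1985 genes. Of 989 genes with more than 1 tested probe, 316 (32.0%) had probes with estimates of both signs. A gene counted as called if at least 1 of its probes was.

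The limma model had a term for OXA (sign by dye) and a term for probe-specific dye bias, with 2 residual degrees of freedom and 3.87 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested probes with a threshold of 0.05. Mean ± SD values are over the 4 arrays, from a single probe per gene. Lists of genes for pathways and cell types were fixed before the data were examined. Of 37 lists, 27 had at least 5 measured genes and were tested with limma's camera on the brightest probe of each gene, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The rule for named genes was fixed at the same time. With fewer than 24 genes called, up to 12 per direction were taken with the smallest moderated p among named probes that had the same sign on all 4 arrays and a change of at least 1.2-fold. Up to 4 members with the smallest p were taken from each list described, and the orexin gene and its receptors were always included.

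The fit was tested on simulated data with 19442 probes, of which 200 were changed by known folds, and noise that was independent between probes. It recovered 2.99% of probes changed 2-fold, 77.6% of those changed 4-fold and 100% of those changed 8-fold, with 3 unchanged probes called. In simulated lists of 14 genes, 1 of 20 lists was shifted by 0.5 (log2). Camera with the preset correlation called the shifted list in 100% of 20 runs and with an estimated correlation in 0%. When noise shared within each list (SD 0.3) was added, the preset setting called 4.45 unshifted lists per run on average.

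Alternatives were no background subtraction, normexp with offset 16, median centring, the scanner's LogRatio, the deposited value table, no filter, a filter on all arrays in both channels, no dye term, a separate-channel analysis, array weights, OXA in Cy5 on all arrays, leaving out each array, an unadjusted threshold with a 1.2-fold minimum, and for lists an estimated correlation, fry and the mean of a gene's probes. Turning the direction of array 2, with the dye term kept, was added after seeing the data. With OXA in Cy5 on all arrays, dye and OXA cannot be told apart, and that fit had no dye term. A slide block could not be made. Plots were drawn with matplotlib 3.10.9.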

Results

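The myometrium, the smooth muscle layer of the uterus, was taken from pigs on days 15 to 16 of gestation and kept as explants for 24 h with or without orexin A (OXA), after 2 h of preincubation. OXA is a peptide made from the prepro-orexin transcript (HCRT) that acts through the receptors encoded by HCRTR1 and HCRTR2. The sample labels give 10 nM OXA, while the series' design text gives 10 µM, and which of them was used is left open here. Each of 4 arrays compared treated with non-treated tissue, with the dyes swapped on arrays 2 and 4. Between 39.9% and 49.7% of 43603 probes were well above background in the OXA channel, and between 41.5% and 61.1% in the non-treated channel.

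The comparison asks which transcripts of the myometrium differ after exposure to OXA. Transcripts of the hypoxia and glycolysis response had positive log2 ratios as a group, with the dyes as labelled. The median log2 ratio over 14 genes averaged 0.31 ± 0.17 (SD of the array medians, n = 4). Camera called this list with a preset correlation, but not with an estimated correlation (adjusted p = 0.935 with an estimated correlation), with OXA in Cy5 on all arrays (adjusted p = 0.932) or with the direction of array 2 turned (adjusted p = 0.0918, an alternative chosen after seeing the data). The estimated setting also called a simulated list shifted by 0.5 in 0% of 20 runs, so its missing call cannot decide. The list was not called by fry either (adjusted p = 0.808), which was not run on simulated lists. DDIT4, a stress-induced inhibitor of mTORC1 signalling, had a log2 ratio of 0.97 ± 0.19 (SD, n = 4), or 1.95-fold, and its 4 probes averaged 0.76 to 0.98. ADM, which encodes the vasodilator adrenomedullin, had 0.57 ± 0.13, and VEGFA, the angiogenic growth factor, had 0.57 ± 0.21 (SD, n = 4). EEF1A1, the translation elongation factor, lay on the other side with -0.64 ± 0.35. Its 18 probes averaged -0.64 to -0.39, and 12 of them were negative on all 4 arrays. PPP1CB, a catalytic subunit of protein phosphatase 1 that acts on myosin light chain, had -0.74 ± 0.21 (SD, n = 4). This was the lowest of its 10 probes, which averaged -0.74 to -0.21, and 3 of them were negative on all 4 arrays.

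None of these single genes passed the test. limma called 0 of 19505 probes and 0 of 1985 genes (lowest adjusted p = 1), with 243 probes at an unadjusted p under 0.05, which is 1.25% of those tested. A separate-channel fit in limma also called 0, with 598 at an unadjusted p under 0.05. In a fit that leaves out 1 array, 1 array is alone in its dye orientation, so the spread comes from the other 2 arrays only. Without array 2 the same model called 260 probes, 78 of them from 30 named genes, against 2, 5 and 8 probes without arrays 1, 3 and 4.

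Log2 ratios were positive on all 4 arrays for 894 tested probes, unnamed ones included. The other genes on the positive side were picked from the named probes among them with a change of at least 1.2-fold. TNFAIP3, an inhibitor of NF-kappaB signalling, had 0.65 ± 0.13, and KLF6, an injury-responsive transcription factor, had 0.64 ± 0.30 (SD, n = 4). ACE, the angiotensin-converting enzyme, had 0.71 ± 0.35, and CPT1A, which brings fatty acids into mitochondria, had 0.81 ± 0.65. GMPPB, an enzyme of GDP-mannose synthesis, had 0.92 ± 0.41. EMP1 (0.74 ± 0.24), CAST, the calpain inhibitor (0.61 ± 0.14), DNMT1, the maintenance DNA methyltransferase (0.52 ± 0.07), and ABCF1 (0.75 ± 0.54) were positive as well. For DNMT1, the 6 probes averaged 0.10 to 0.52, and 4 of them were positive on all 4 arrays.

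Genes with negative log2 ratios on all 4 arrays included ACSL1, which activates fatty acids (-0.58 ± 0.31, SD, n = 4), and PHYH, a peroxisomal enzyme of fatty acid oxidation (-0.46 ± 0.23). CFB, complement factor B, had -0.61 ± 0.30, ACKR1, a decoy receptor for chemokines, had -0.45 ± 0.32, and LCN2, a siderophore-binding lipocalin, had -0.51 ± 0.36. CTNNB1, which encodes beta-catenin, had -0.50 ± 0.47, and PPP2CA, the catalytic subunit of protein phosphatase 2A, had -0.41 ± 0.06. ZFAND5 (-0.52 ± 0.18), the splicing factor SRSF1 (-0.47 ± 0.19) and RAB22A (-0.43 ± 0.17) had log2 ratios of similar size. For ZFAND5, SRSF1, RAB22A and, on the positive side, ABCF1, other probes of the gene differed in sign. limma's adjusted p was 1 for each of these 24 genes. When OXA is taken to be in Cy5 on all 4 arrays, as the labelling protocol words it, 9 of the 12 genes on the positive side turn negative, DDIT4 among them at -0.05. On the negative side, ACSL1 (0.21) and PHYH (0.06) turn positive. Since the genes were picked for a common sign on all 4 arrays, this reading sets opposite values against each other in every mean.

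**Figure D1:**
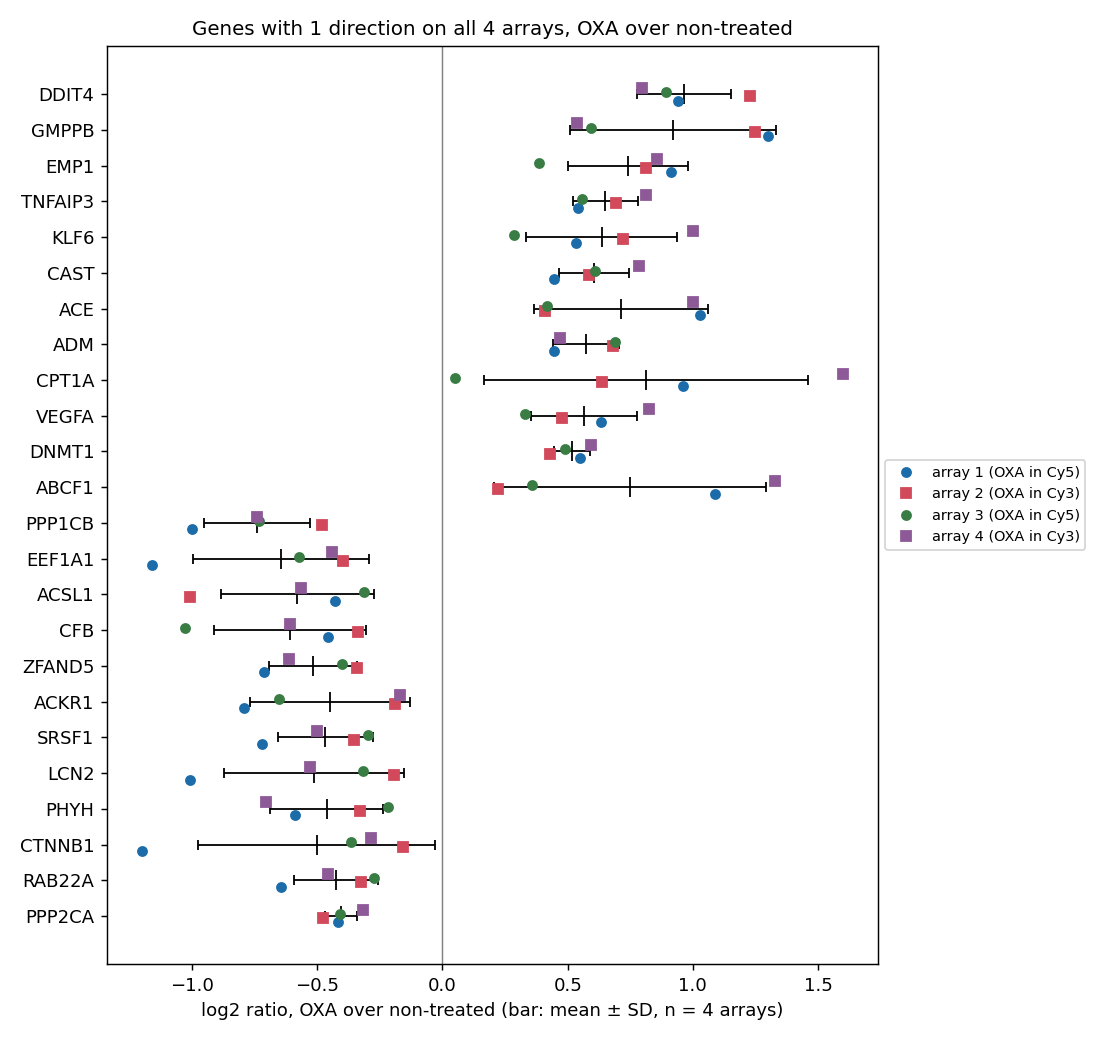
Log2 ratio of OXA-treated over non-treated tissue (x axis) for 24 genes (y axis), the 12 with the smallest p in each direction among named genes with the same sign on all 4 arrays and a change of at least 1.2-fold. Points are single arrays, circles with OXA in Cy5 and squares with OXA in Cy3, and bars are mean ± SD (n = 4). DDIT4 lies between 0.80 and 1.23 on the 4 arrays, and PPP2CA between -0.48 and -0.32.

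Of 27 gene lists tested, camera called 6, of which 4 were higher and 2 lower with OXA. Below, rose and fell give the direction of this preset call alone. The estimated inter-gene correlations of the 6 ran from 0.131 to 0.703, above the preset 0.01. With simulated noise shared within lists (SD 0.3), the preset setting called 4.45 unshifted lists per run, so shared noise could give such calls. The estimated setting called the shifted simulated list in 0% of runs, so its missing calls cannot decide. With fry, 0 of the 27 lists were called (lowest adjusted p = 0.808). The hypoxia and glycolysis list rose (adjusted p = 0.000153, but adjusted p = 0.935 with an estimated correlation). All 14 of its measured members had positive estimates, and the array medians were 0.40, 0.07, 0.28 and 0.46 on arrays 1 to 4. DDIT4, with its brightest probe, was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0284), and 0 passed over all probes. Besides DDIT4, ADM and VEGFA, the glycolytic enzyme ALDOC had 0.49 ± 0.21 (SD, n = 4), with positive values on all 4 arrays. The list is not called with OXA in Cy5 on all arrays (adjusted p = 0.932) or with array 2 turned (adjusted p = 0.0918). Markers of macrophages were also higher on arrays 1, 3 and 4, with medians of 0.48, 0.95 and 0.53, and lower on array 2, with -0.38.

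The endoplasmic reticulum stress list rose by the same test (adjusted p = 0.0105, and adjusted p = 0.935 with an estimated correlation), with 7 of 8 members positive. XBP1, a transcription factor of the unfolded protein response, had 0.44 ± 0.21 (SD, n = 4). CALR, the chaperone calreticulin, had 0.59 ± 0.48, and DDIT3, a stress-induced transcription factor, had 0.63 ± 0.69, both negative on array 2. The array medians of the list were 0.80, -0.09, 0.17 and 0.54, and those of macrophage markers followed the same signs. Adjusted over the list alone, 0 members passed. The list is not called with OXA in Cy5 on all arrays or, chosen after seeing the data, with array 2 turned. The call is lost without array 1 (adjusted p = 0.274), array 2 (adjusted p = 0.0518) or array 4 (adjusted p = 0.114), and with the scanner's own log ratios (adjusted p = 0.137).

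Collagens and other matrix genes fell as a list (adjusted p = 0.000445, and adjusted p = 0.935 with an estimated correlation), with 12 of 16 members negative and array medians of -0.26, -0.31, 0.17 and -0.32. SPARC, a collagen-binding matrix protein, had -0.36 ± 0.19 (SD, n = 4). Its 7 probes averaged -0.62 to -0.06, and 3 of them were negative on all 4 arrays. LUM, a collagen-binding proteoglycan, had -0.36 ± 0.51, and TNC, tenascin C, had -0.36 ± 0.53, both positive on array 3. The contractile list fell as well (adjusted p = 0.0384, and adjusted p = 0.935 with an estimated correlation), with 10 of 14 members negative and medians of 0.08, -0.20, 0.21 and -0.45. These medians were positive on arrays 1 and 3, with OXA in Cy5, and negative on arrays 2 and 4, with OXA in Cy3. Dye bias would give such signs, and its part stays open. TPM2, a tropomyosin, had -0.31 ± 0.10 and was negative with all 5 probes on every array, while ACTN1, an actin cross-linker, had 0.40 ± 0.13 (SD, n = 4). MYL9, the regulatory myosin light chain, had -0.28 ± 0.50. Adjusted over the list alone, 0 members of either list passed. Markers of uterine epithelium were higher on arrays 2 and 4, with medians of 1.69 and 0.78, and these were the arrays with the lowest medians of both lists. Markers of fibroblasts and stroma, with 4 measured genes and no test, had medians of -0.17, -0.26, -0.007 and -0.25. That list shares DCN and LUM with the collagen list. The collagen call is lost without array 1 (adjusted p = 0.089) or array 4 (adjusted p = 0.165). The contractile call is lost in 12 of the 18 alternatives fixed beforehand, among them those without array 1, 2 or 4 (adjusted p = 0.572, 0.0518 and 0.695). With OXA in Cy5 on all arrays, the contractile list is called higher (adjusted p = 0.0205), and the collagen list has a positive direction without a call (adjusted p = 0.256). Dye and OXA cannot be told apart under that reading.

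Of the markers of other cell types, those of macrophages and of uterine epithelium rose as lists. The macrophage list (adjusted p = 0.00593, and adjusted p = 0.935 with an estimated correlation) had 10 of 11 members positive. VSIG4, a complement receptor of tissue macrophages, had 0.64 ± 0.62, AIF1 had 0.50 ± 0.59, and the complement component C1QB had 0.66 ± 1.05 (SD, n = 4), each negative on array 2. The epithelial list (adjusted p = 0.000645, and adjusted p = 0.935 with an estimated correlation) had array medians of 0.08, 1.69, -0.63 and 0.78. MUC4, a membrane mucin, had 0.61 ± 1.14 and KRT8, an epithelial keratin, had 0.49 ± 0.98 (SD, n = 4), with 2.06 and 1.38 on array 2 and -0.50 and -0.71 on array 3. Adjusted over the list alone, 0 members of either list passed. Endothelial markers had medians of -0.37, -0.03, 0.07 and 0.45 and were not called (adjusted p = 0.591). The epithelial call is lost without array 2 (adjusted p = 0.863) and turns lower with OXA in Cy5 on all arrays, and the macrophage call is lost without array 3 (adjusted p = 0.688) or array 4 (adjusted p = 0.515).

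**Figure D2:**
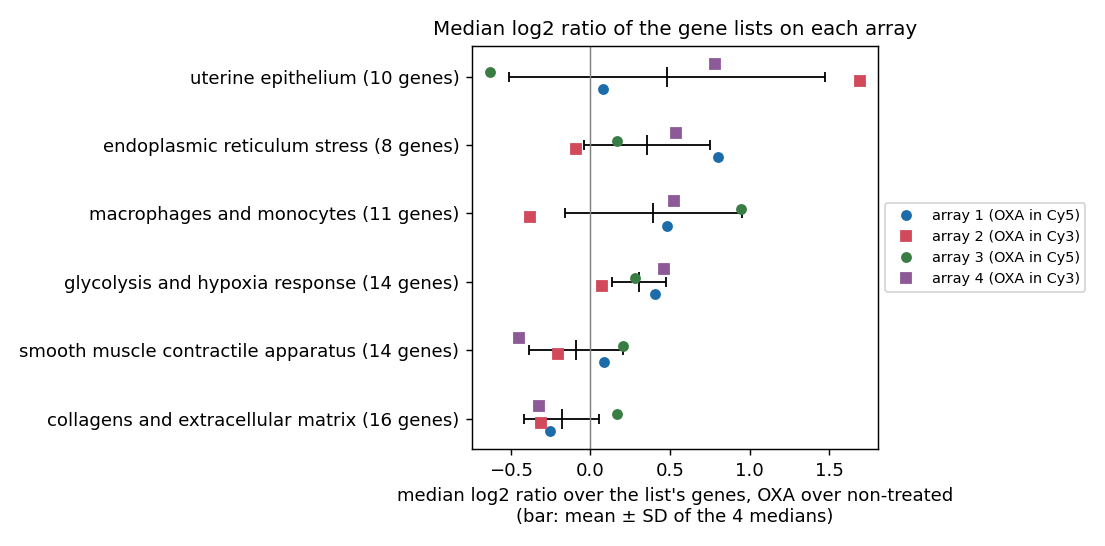
Median log2 ratio of OXA-treated over non-treated tissue (x axis) for the 6 gene lists called by camera with the preset correlation (y axis, with the number of measured genes). Points are single arrays and bars are the mean ± SD of the 4 array medians. The hypoxia and glycolysis medians lie between 0.07 and 0.46, and those of uterine epithelium between -0.63 and 1.69.

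Lists of hormone receptors, prostaglandin and steroid synthesis, and cytokines were not called. Receptors for uterotonic hormones, gap junctions and ion channels had array medians over 16 genes that averaged 0.09 ± 0.12 (camera adjusted p = 0.896). The oxytocin receptor OXTR had 0.21 ± 0.22 (SD, n = 4), and the gap junction gene GJA1 had 0.24 ± 0.24. The endothelin receptors EDNRA and EDNRB had 0.23 ± 0.13 and 0.22 ± 0.18 (SD, n = 4), EDNRB with a value on array 1 that stood apart. Among 10 prostaglandin genes (adjusted p = 0.896), PTGES, a prostaglandin E synthase, had 0.31 ± 0.34. Among 10 steroid synthesis genes (adjusted p = 0.896), aromatase (CYP19A1) had 0.43 ± 0.33 and was positive on all 4 arrays. The oestrogen receptor ESR1 had 0.28 ± 0.19 (SD, n = 4) within a list of 13 steroid receptors and coregulators (adjusted p = 0.896). Of 28 cytokine and chemokine genes (adjusted p = 0.896), CXCL8 had 0.50 ± 0.32 and NFKBIA, an inhibitor of NF-kappaB, had 0.40 ± 0.35, both positive on all 4 arrays. In each of these groups, 0 members passed when adjusted over the list alone.

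Of the orexin system itself, HCRT was well above background on all 4 arrays in both channels, with a log2 ratio of 0.04 ± 0.31 (SD, n = 4). The probes for HCRTR1 and HCRTR2 were not well above background on any array in either channel, so no ratio is given for the receptors.

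The arrays differed from each other in the direction of many probes. Across tested probes, which are not independent replicates, log2 ratios of array 1 correlated with those of array 4 at r = 0.68 and with those of array 2 at r = -0.57, and arrays 2 and 4, which share a dye orientation, correlated at r = -0.42. The log2 ratio had the same sign on all 4 arrays for 7.97% of probes, where 12.5% would share it by chance. With array 2 turned, 34.5% of probes share a sign, and camera calls 3 lists, macrophage markers higher (adjusted p = 0.0145) and collagens (adjusted p = 0.0351) and calcium and cAMP signalling (adjusted p = 0.0108) lower. The calls of the hypoxia and contractile lists (adjusted p = 0.0918 for each), the endoplasmic reticulum stress list (adjusted p = 0.22) and the epithelial list (adjusted p = 0.969) are then lost. The smallest two-sided p that an exact test on the signs of 4 arrays allows is 0.125. The dye term called 0 probes in limma, with 277 at an unadjusted p under 0.05. Averaging the same Cy5 over Cy3 ratios, the fit with OXA in Cy5 on all arrays gave 4 called lists in camera. Dye shifts of whole lists therefore stay open.

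**Figure D3:**
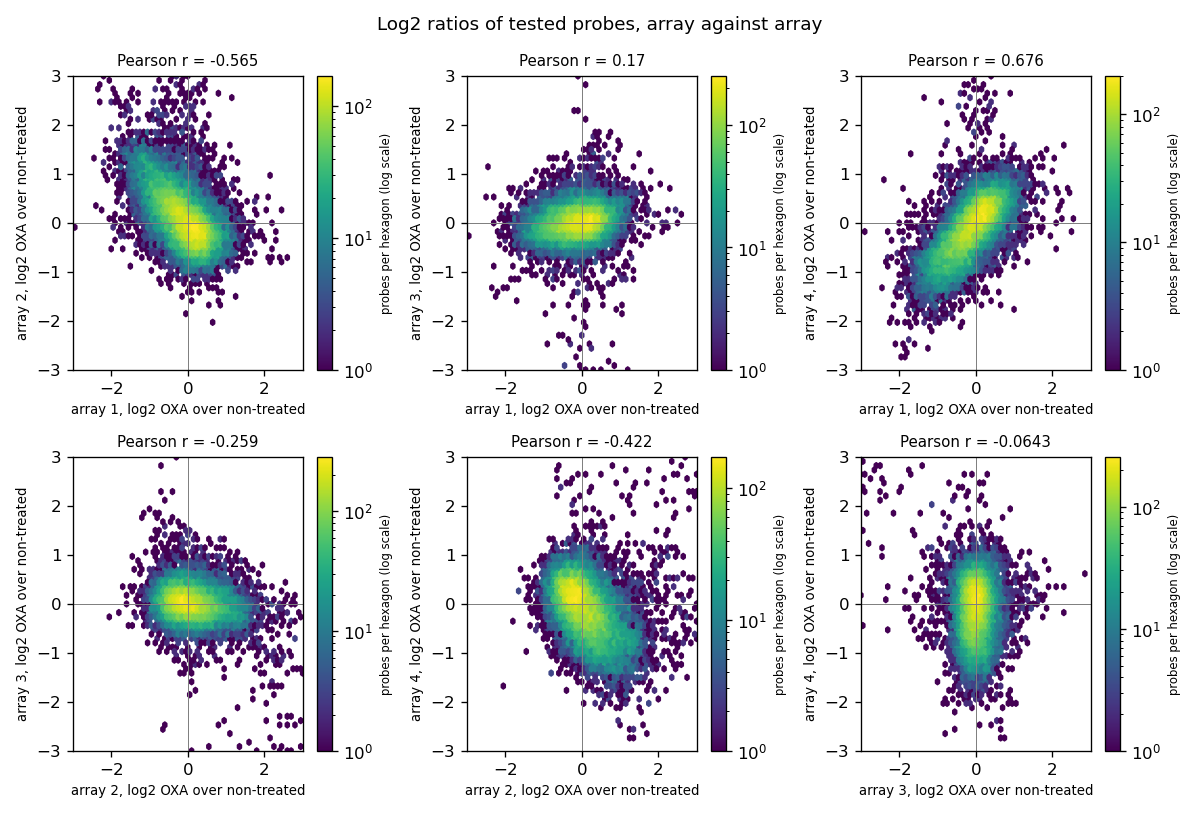
Log2 ratio of OXA-treated over non-treated tissue for each tested probe on 1 array (x axis) against another (y axis), for the 6 pairs of arrays. Colour is the number of probes per hexagon on a log scale, probes beyond the axes are not drawn, and Pearson r stands above each panel, from -0.565 for arrays 1 and 2 to 0.676 for arrays 1 and 4.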

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

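The tests in this part, turning array 2 included, were chosen after the results were seen, except Dixon's ratio, the surface test, the reading with OXA in Cy5 on all arrays, the fit without array 2 and the fit without a dye term as labelled. In 6 of 109 sets of 4 array values, 1 array stood apart from the other 3 by Dixon's ratio, and chance sets apart about 5%. EDNRB was 0.48 on array 1 and 0.12 to 0.15 on the others. HSP90AA1 was 0.0371 on array 2 and -0.50 to -0.46 elsewhere, and CXCL11 was 2.77 on array 2 and -0.34 to 0.13 elsewhere. CTGF was -0.0924 on array 4 and 0.58 to 0.71 on the others. The collagen and matrix list had a median of 0.165 on array 3 and -0.32 to -0.26 on the others. The SD of log2 ratios over probes was 0.328 on array 3 and 0.546 to 0.557 on the others.

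Log2 ratios on array 2 correlated negatively with those on arrays 1 and 4. Dye bias of probes would make Cy5 over Cy3 ratios correlate positively between all arrays. The lowest of the 6 correlations was -0.676, for arrays 1 and 4, and arrays 2 and 4 had -0.422, which argues against dye bias as the only source. Arrays 1 and 2 had 0.565 and arrays 2 and 3 had 0.259, the sign that dye bias would give, so it may contribute. A correlation of arrays 1 and 2, as labelled, that stayed at -0.562 after a smooth surface over the spots was removed argues against uneven hybridisation. A recorded orientation of array 2 that is the wrong way round may account for the pattern. Array 3 correlated with array 1 at 0.17 and with array 2 at -0.259, signs that go with this reading. With array 4 it correlated at -0.0643, too close to 0 to decide. With array 2 turned 3 lists are called, without the hypoxia (adjusted p = 0.0918), contractile, endoplasmic reticulum stress and epithelial lists. In fits without a dye term, 394 probes had an unadjusted p under 0.05 as labelled (4 of 8 sign assignments gave at least as many) against 5426 with array 2 turned, the highest other, which restates this negative correlation, and 8 assignments are too few for a share under 0.05. An unequal response of the animals and unequal RNA quality of the paired extracts stay open and were not tested.

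The hypoxia and glycolysis list had medians above 0 on all 4 arrays as labelled. Of the 27 tested lists, 5 had medians of 1 sign on all 4 arrays, this list among them. On array 2 its median lay at percentile 80.8 of random lists matched on intensity, against 98.4 to 99.7 on the others. Of its 14 members, 5 were positive on every array. Probe-specific dye bias alone would give opposite signs in the 2 dye orientations, and the median over members was above 0 in both. Its lower bound was 0.116 on the 2 arrays with OXA in Cy3, from a bootstrap over members, which are not independent. That restates a pattern picked for medians above 0 on all 4 arrays, so it is no separate test. The bootstrap interval was 0.359 to 0.495 on array 4 but -0.224 to 0.476 on array 2, and a part played by dye bias stays open. A larger share of macrophages could contribute, and on array 2, where the macrophage median was -0.38, the lower bound for the list was -0.224, which leaves this open. In fits without a dye term, the camera z of this list was 4.67 as labelled and at most 2.34 in the other sign assignments (1 of 8 as large). The list was picked for medians above 0 on all 4 arrays as labelled. Other assignments set these medians against each other, so the z is no separate test. The number of called lists was 5 as labelled and at most 7 in the others (2 of 8 as large). For both counts, 8 assignments are too few for a share under 0.05. With array 2 turned, a reading left open above, the list is not called (adjusted p = 0.0918), while without array 2 it is (adjusted p = 0.0114), and an effect of OXA on these genes stays open.

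With the dyes as in the sample labels, markers of uterine epithelium differed between arrays in both directions, and all 3 explanations stay open. Adhering endometrium in unequal amounts between paired pieces is a candidate explanation, with 10 of 10 markers above 0 on array 2 and 0 of 10 on array 3 as labelled. UABP2, planned as a marker, was left out of the list because its name here is UABP-2. A probe of it, seen after it was called without array 2, had -2.31, 2.42, -0.84 and -0.83 on arrays 1 to 4. It lay below 0 on array 4, where the list's median was 0.78. A common effect of OXA has against it the median of -0.63 on array 3, at percentile 0 of random lists matched on intensity, beside 1.69 on array 2. With OXA in Cy5 on all arrays the medians become 0.08, -1.69, -0.63 and -0.78, no array clearly opposes the others, and the list is called lower (adjusted p = 5.02e-16), so both readings depend on the recorded dyes. Dye bias could contribute, since these Cy5 over Cy3 medians were below 0 on arrays 2, 3 and 4. Singled out after their values were seen, RBP4 (-1.72, 2.17, -1.56 and 1.38 on arrays 1 to 4 as labelled) and EPCAM (-0.90, 2.30, -1.24 and 1.18) were higher in Cy3 on every array. Against that, 6 of 10 markers were higher in Cy5 on array 1. The gap of 0.137 between the bootstrap intervals of arrays 1 and 2 does not decide, since members are not independent.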

How the results depend on the processing

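limma called 0 probes under every alternative except median centring (1 probe and 1 gene, CFL2), leaving out an array, and the unadjusted threshold with at least 1.2-fold (243 probes, 51 genes). Without 1 array the count ran from 2 to 260 probes and from 0 to 30 genes, highest without array 2. The dye term called 438 probes under median centring, which leaves intensity-dependent dye bias in place, and 4 to 844 without 1 array. The number of called lists went from 6 to 3 in the separate-channel analysis and to 3 to 5 without 1 array, where some of the called lists were not among the 6. It was 0 with an estimated correlation (adjusted p = 0.935 for each of the 6) and 0 with fry (adjusted p = 0.808 for each). In simulated data the estimated setting called the shifted list in 0% of runs, so its count of 0 cannot decide. The share of probes with a common sign was 11.9% to 42.5% without 1 array, highest without array 2, and fewer arrays raise chance agreement.

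Turning array 2 was chosen after seeing the data, because its direction is in doubt. It left 0 called probes, raised the share with a common sign to 34.5% and left 3 called lists. The hypoxia and contractile lists then lost their calls (adjusted p = 0.0918 for each), as did the endoplasmic reticulum stress list (adjusted p = 0.22) and, with a lower direction, the epithelial list (adjusted p = 0.969), while the calcium and cAMP signalling list was called lower (adjusted p = 0.0108).

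The hypoxia and glycolysis list kept its call in 15 of the 18 alternatives fixed beforehand, each of them with the preset correlation. With OXA in Cy5 on all arrays it lost the call (adjusted p = 0.932), as did the endoplasmic reticulum stress list (adjusted p = 0.889). Dye and OXA cannot be told apart under that reading, so its calls may be shifts by dye. Under that reading the contractile list turned higher (adjusted p = 0.0205), the collagen list turned to a higher direction without a call (adjusted p = 0.256), the epithelial list turned lower (adjusted p = 5.02e-16), and the ribosomal list was called higher (adjusted p = 5.33e-12). The contractile list lost its call without background subtraction (adjusted p = 0.0635), with median centring (0.293), the scanner's LogRatio (0.196), the deposited table (0.259), the strict filter (0.0585), no dye term (0.0512) and separate channels (0.122). The endoplasmic reticulum list lost it with the scanner's LogRatio (adjusted p = 0.137), the epithelial list with median centring (0.075) and separate channels (0.162), and the macrophage list with separate channels (0.0735). Without 1 array, adjusted p ran from 0.0121 to 0.695 for the contractile list, 0.000802 to 0.165 for collagens, 0.00153 to 0.274 for endoplasmic reticulum stress, 1.13e-13 to 0.688 for macrophages and 3.17e-09 to 0.863 for epithelium. The interferon list ran from 0.012 (without array 4) to 0.75, and the calcium and cAMP signalling list from 0.00781 (without array 2) to 0.75. Of 360 values of the 24 genes with a common sign under those alternatives, 11 had the opposite sign, all with OXA in Cy5 on all arrays. These genes were picked for a common sign on every array. Fits without an array, with array weights or without a dye term therefore could not turn it. Other causes were not tested. Ratios of probes near background are drawn toward 0 by the offset, which limits what can be seen of the orexin receptors.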

Other observations

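The genes below were called without array 2 and were chosen after their values were seen. Leaving out this array was planned, with 1 residual degree of freedom, and 213 of the 260 probes were lower with OXA. Of these probes, 232 (89.2%) had the opposite sign on array 2, and 211 had the same sign on arrays 1, 3 and 4. SPARCL1, for example, was called lower with positive values on array 3. In this fit array 4 was alone in its dye orientation, so the spread came from arrays 1 and 3. The p-values therefore do not measure agreement of 3 arrays, and values of 1 probe per gene are given instead. POSTN, the matrix protein periostin, had -1.34, -0.88 and -2.04 on arrays 1, 3 and 4 against 1.75 on array 2. The adhesion genes ITGAV (-1.17, -0.52 and -1.09) and VCAM1 (-0.78, -0.50 and -1.51) were also negative on arrays 1, 3 and 4 and positive on array 2. The cAMP phosphodiesterase PDE4B (-1.17, -0.48 and -1.86) had the same signs. So had SF3B1 (-1.12, -0.35 and -1.36) and SRSF11 (-1.25, -0.36 and -1.53), which encode splicing proteins. CLK1, a kinase of splicing factors (-1.7, -0.28 and -1.51), and EIF4A2, a helicase of translation initiation (-1.37, -0.56 and -1.7), had them too. On the other side, MMP9, a gelatinase, had 0.72, 1.40 and 1.03 on arrays 1, 3 and 4 and -0.38 on array 2. C5AR1, the complement C5a receptor (1.5, 1.42 and 0.69), and C1QB (0.695, 1.81 and 0.844) were likewise negative on array 2. Macrophage markers were higher on the same 3 arrays.

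SLPI, a protease inhibitor, had log2 ratios of 2.50 to 3.55 on array 2 with its 7 probes. They were negative on the others, with -2.34 to -1.46 on array 1, -1.49 to -1.01 on array 3 and -0.83 to -0.57 on array 4. The pericyte and vascular smooth muscle markers, with 4 measured genes and no test, had medians of -0.38, 0.87, 0.44 and -0.67 on arrays 1 to 4. The 28 ribosomal protein genes had medians of 0.62, -0.40, 0.22 and -0.07 and were not called (adjusted p = 0.896). The 10 angiogenic genes had medians of 0.27, 0.23, 0.32 and 0.14, positive on all 4 arrays, and were not called (adjusted p = 0.419). On array 4 their median lay at percentile 52.9 of random lists matched on intensity. ADM and VEGFA belong to both this list and the hypoxia list, so the lists are not separate observations. GAPDH, often used as a reference gene, had 1.10, -0.78, 0.78 and -0.31. Like the contractile medians, the ribosomal and GAPDH values were positive on arrays 1 and 3, with OXA in Cy5, and negative on arrays 2 and 4.

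The smallest unadjusted p in limma belonged to a CFL2 probe with 5.11 on array 3, -0.10 on array 2, -0.74 on array 4 and no usable spot on array 1, while the other 10 CFL2 probes reached at most 0.68 on array 3.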
